A study of Homo sapiens with 16 samples.

How the data were processed

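RNA was sequenced from PC3, an established human prostate cancer cell line, grown as monolayer cells or as xenograft tumors, that is, tumors formed by the human cells in a host animal. Each setting held control and DDX4-null libraries, which gave 4 groups of 4 libraries. The labels do not say whether libraries of a group came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

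The deposited values were raw read counts per Ensembl gene for 20356 genes in 16 libraries, and they were used as the authors deposited them. Per the labels' protocols, total RNA was treated with DNase and libraries were made with the Illumina TruSeq Stranded mRNA kit. Per the submitters' processing notes, the tools were Trimmomatic 0.39, STAR 2.7.10a and featureCounts 2.0.3, and the genome build was GRCh37. The strand setting, the gene annotation and any removal of host reads are not given in the sources used here. Reads of genes with close copies, such as keratins, histones, ribosomal proteins and zinc finger genes, can be shared between copies, and reads of the host can be counted on human genes. A table of gene names gave symbols for 19446 IDs, GENCODE v29 gave 65 more, and 845 had none. Unnamed IDs stayed in the tests and held 0.211% to 0.310% of each library's counts. Chromosome names and gene order came from GENCODE v29 on GRCh38, matched by Ensembl ID, and no coordinates are given.

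Library totals ran from 12204254 to 25443952 counts. A count of 0 allows up to 3 counts, which is 0.118 to 0.246 CPM per library, where CPM are counts scaled to a library of 1e6. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. No pair of replicates agreed within sampling noise, so no library was counted as a copy of another.

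Before the data were examined, the comparisons, the tests, 34 gene lists, the rule for named genes and most alternatives were fixed. Gene tests used the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter and Benjamini-Hochberg adjustment at 0.05. DDX4-null was compared with control in the 8 monolayer libraries and in the 8 tumor libraries, control tumors with control cells in 8 libraries, and the difference between both genotype effects in a 4-group model of all 16 libraries. Log2 changes are given with their standard error (SE), levels as mean TMM-scaled CPM with SD, and n is 4 libraries per group. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Members of a list were also adjusted over the list alone. DDX4 itself was compared by an exact two-sided permutation test of log2(CPM + 0.5).

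Named genes followed a rule. For each genotype comparison it took the 8 largest rises and the 8 largest falls among called genes with at least 1 CPM in the higher group and no overlap between groups, which chance gives for 2.86% of genes with 4 libraries against 4. It also took up to 2 called members with the smallest p of each list, or up to 4 where the list passed. It added the genes with the largest changes of one direction and of opposite directions in both settings, 8 genes for the difference between settings, and 12 for control tumors against control cells. Clone-type names and IDs with no symbol were counted and not named. Some single-gene results are not reported here, while the counts include them.

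The steps were tested on simulated counts with 200 changed genes. For edgeR in monolayer, 67.2% of genes changed by 0.5 on the log2 scale were recovered, and 100% of those changed by 1, with 9.18% of calls false. In tumors these were 38.8% and 82.1%, with 8.12% of calls false. For the difference between settings they were 13.4% and 77.6%, with 0.806% false. For control tumors against control cells they were 67.2% and 98.5%, with 7.33% false. DESeq2 1.42.0 gave 11.9% false calls in monolayer and 16.2% in tumors. In a simulation with a shifted chromosome, 415 monolayer calls were false without centring and 6 with it.

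The alternatives were DESeq2, other size factors, library totals, other filters, a replicate block, a model of all 16 libraries, a 2-fold threshold, list tests with an estimated correlation or on ranks, and leaving out each library. Centring of changes by chromosome, or on a running median of 51 neighbouring genes, and 2 further list tests in tumors were added after seeing the data, with stromal markers as a covariate and on genes of at least 1 CPM in monolayer.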

Results

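The data asked what the germ cell RNA helicase DDX4 does to gene expression in PC3 prostate cancer cells, in culture and in xenograft tumors. RNA was sequenced from 4 control and 4 DDX4-null libraries in each setting. Control monolayers held 14368124 to 18836982 counts per library and DDX4-null monolayers 16151344 to 21763745. Control tumors held 13480294 to 25443952 counts and DDX4-null tumors 12204254 to 17961710. The first principal component carried 56.8% of the variance and the next 29.9%. Pearson correlations of replicates across genes lay between 0.971 and 0.995.

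**Figure D1:**
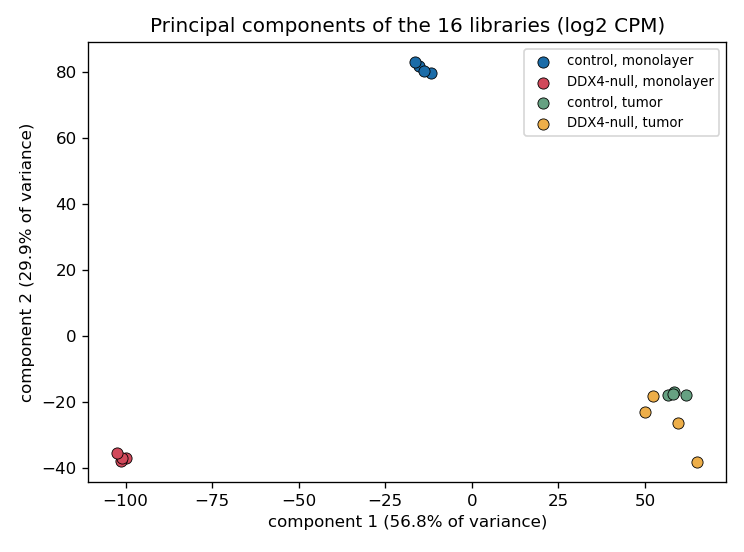
Each point is 1 of the 16 libraries on the first and next principal components of log2 CPM, which carried 56.8% and 29.9% of the variance. Control and DDX4-null monolayer libraries lie far apart, and the 8 tumor libraries lie near each other.

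DDX4 RNA was near the counting floor in all groups. The 4 control monolayer libraries held 0, 4, 1 and 5 DDX4 counts, and the DDX4-null monolayers 2, 4, 0 and 1. Control tumors held 5, 2, 3 and 3 counts, and DDX4-null tumors 3, 2, 2 and 4. The group sums of 10, 7, 13 and 11 counts corresponded to 0.151, 0.0942, 0.176 and 0.177 CPM. Neither the monolayers (exact two-sided permutation p = 0.543) nor the tumors (exact p = 0.971) showed a difference, and the smallest p the design allows is 0.0286. A change of DDX4 RNA was not detectable at this depth, so its level does not check the labels.

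DDX4-null monolayer cells had lower inflammatory cytokine and interferon-response RNA and higher cell cycle RNA than control cells. Only the cytokine list also passed with an estimated correlation, and interferon response (adjusted p = 0.166), S phase (adjusted p = 0.182) and G2 and mitosis genes (adjusted p = 0.199) did not. The interleukin IL6 went from 221 ± 29.4 to 11.6 ± 0.971 CPM (SD, n = 4), a log2 change of -4.26 ± 0.12 (SE). PTGS2, the inducible cyclooxygenase, went from 126 ± 6.60 to 1.08 ± 0.273 CPM. The proliferation marker MKI67 rose from 72.3 ± 3.68 to 218 ± 16.2 CPM, and TOP2A, a DNA topoisomerase, from 115 ± 8.97 to 358 ± 32.2 CPM. Of 13006 genes tested with edgeR, 4555 rose and 4201 fell at an adjusted p under 0.05, and 1689 and 1126 of them changed at least 2-fold. With library totals in place of TMM, 5030 rose and 3705 fell. Whole chromosomes also differed between these groups, as given below. The monolayer changes therefore cannot be told apart from a difference of cell population that is unrelated to DDX4.

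Among NF-kB targets and inflammatory cytokines, 26 of 28 tested genes fell and 2 rose, and adjusted over the list alone the counts were also 26 and 2. The chemokine CXCL5 changed by -9.45 ± 0.16 on the log2 scale and the granulocyte growth factor CSF3 by -5.02 ± 0.17. The list test gave an adjusted p of 6.0e-26, and it also passed with an estimated correlation (adjusted p = 0.0080). Of 32 type I interferon response genes, 29 fell and 1 rose, with the same counts adjusted over the list alone (adjusted p = 1.5e-12). IFI44L changed by -4.07 ± 0.13, the RNA sensor OAS2 by -2.28 ± 0.10 and IFI6 by -2.70 ± 0.12. The interferon list did not pass with an estimated correlation (adjusted p = 0.166).

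S phase genes rose in 20 of 23 cases and fell in 1, and adjusted over the list alone 21 rose and 1 fell (adjusted p = 3.7e-06). The replication helicase subunit MCM3 changed by 1.96 ± 0.10, the ribonucleotide reductase subunit RRM2 by 1.52 ± 0.09 and GINS2, another replication helicase factor, by 2.41 ± 0.18. Of 25 G2 and mitosis genes 24 rose, also adjusted over the list alone (adjusted p = 1.1e-08), among them the spindle checkpoint kinase BUB1B at 1.54 ± 0.10 and NUSAP1 at 1.63 ± 0.10. With an estimated correlation neither passed (adjusted p = 0.182 for S phase and adjusted p = 0.199 for G2 and mitosis). Of 17 Wnt pathway genes 14 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.00027, and adjusted p = 0.182 with an estimated correlation). RNF43, a membrane ubiquitin ligase that limits Wnt signalling, changed by 2.58 ± 0.14, the ligand WNT5A by 2.01 ± 0.13 and the receptor FZD1 by 1.40 ± 0.13. LEF1, a transcription factor of the pathway, had 1 count in the control group and 10.4 ± 1.90 CPM in DDX4-null cells, 675-fold higher with a 95% counting interval of 121 to 26680.1.

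Replication-dependent histone genes, whose RNAs mostly lack a poly(A) tail, fell in 9 of 9 cases, also adjusted over the list alone (adjusted p = 0.0038, and adjusted p = 0.311 with an estimated correlation). H1-2 changed by -1.20 ± 0.11 and H4C8 by -1.30 ± 0.10. Of 24 genes of the unfolded protein and integrated stress response 16 fell and 3 rose, also adjusted over the list alone (adjusted p = 0.0178, and adjusted p = 0.343 with an estimated correlation). The protein disulfide isomerase PDIA4 changed by -2.15 ± 0.11 and the chaperone DNAJB9 by -1.93 ± 0.11, while SESN3, a stress-response gene of the sestrin family, rose by 7.04 ± 0.29. PDIA4 and DNAJB9 are on chromosome 7 in GENCODE v29 (GRCh38), and changed by -1.43 and -1.20 after centring by chromosome. Of 16 angiogenesis factors 11 fell and 3 rose, also adjusted over the list alone (adjusted p = 0.0178, and adjusted p = 0.195 with an estimated correlation). The semaphorin SEMA3C changed by -2.81 ± 0.12, the lymphatic growth factor VEGFC by -1.55 ± 0.11 and the co-receptor NRP1 by -1.46 ± 0.09, and NRP2 rose by 1.49 ± 0.11.

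**Figure D2:**
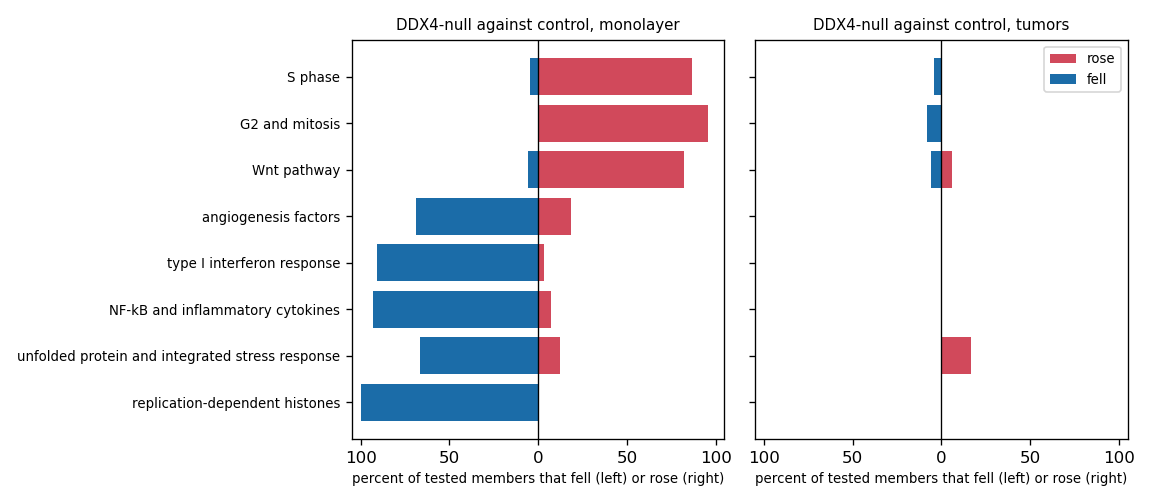
Bars give the percent of tested members of 8 gene lists that rose (right) or fell (left) in DDX4-null against control libraries, in monolayer (left panel) and tumors (right panel), at an adjusted p under 0.05. In monolayer 26 of 28 NF-kB and cytokine genes fell and 24 of 25 G2 and mitosis genes rose, and in tumors at most 4 members of any of these lists passed in one direction.

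The 8 largest rises in DDX4-null cells were mostly genes with 0 counts in the 4 control libraries. CRMP1, a neuronal protein of the response to semaphorins, was at least 857-fold higher than the floor of 3 counts over the group. The adhesion genes CADM1 and NCAM1 were at least 598-fold and 418-fold higher, the retinoic acid receptor RARB at least 411-fold, RAI2 at least 471-fold, CTDSPL at least 379-fold and FXYD6 at least 364-fold. LCP1, an actin-bundling protein of leukocytes, rose from 0.150 ± 0.0650 to 477 ± 23.4 CPM. The 8 largest falls held the mucin MUC5B, from 492 ± 93.9 to 0.344 ± 0.161 CPM, and CXCL5. EVC2, ASB15, ZNF222 and ZNF268 had 0 counts in DDX4-null cells and were at least 91.9-fold, 79.3-fold, 64.3-fold and 50.3-fold lower. ZSCAN18 was 610-fold lower (95% counting interval 169 to 5034.8) and the adhesion molecule VCAM1 433-fold lower (interval 77.7 to 17089.5).

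The epithelial, mesenchymal, hypoxia and germ cell lists held genes that moved in both directions and did not pass. Of 17 epithelial genes 10 rose and 5 fell, with the splicing factor ESRP1 at 6.25 ± 0.15 and the tight junction gene CLDN1 at -2.52 ± 0.10 (adjusted p of the list 0.434). Of 22 mesenchymal genes 10 rose and 9 fell. Of 28 hypoxia and glycolysis genes 6 rose and 10 fell, or 9 adjusted over the list alone, with the carbonic anhydrase CA9 at -7.27 ± 0.30. In the germ cell and piRNA list 3 of 8 tested genes rose and 3 fell, with PLD6, a mitochondrial protein of the piRNA pathway, at 2.15 ± 0.13. No named monolayer gene lost its call when 1 library was left out.

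DDX4-null tumors differed from control tumors in 270 of 12942 genes, of which 127 rose and 143 fell, and 38 and 28 changed at least 2-fold. TCN1, a vitamin B12 binding protein, rose from 0.370 ± 0.288 to 19.8 ± 8.62 CPM, a log2 change of 5.57 ± 0.45. The keratin KRT75 rose from 4.13 ± 0.725 to 18.7 ± 6.61 CPM and CD33, a sialic acid receptor of myeloid cells, from 1.41 ± 0.616 to 6.70 ± 1.49 CPM. The metalloprotease ADAM12 fell from 7.33 ± 1.90 to 1.31 ± 0.519 CPM, and the cadherin CDH7 from 1.19 ± 0.300 to 0.160 ± 0.0756 CPM. HORMAD2, a meiosis gene, had 1 count in DDX4-null tumors and was 112-fold lower (95% counting interval 20.1 to 4415.9), and LINC03010 had 0 counts and was at least 25.4-fold lower. With ZFPM2 at 2.46 ± 0.29, these 8 of the 38 genes named in tumors kept their call in every fit that left out 1 library.

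The other named tumor genes lost their call in at least 1 such fit. Among them KIRREL3 rose by 3.44 ± 0.51, SHISA2 by 2.51 ± 0.40, SERPINB2 by 2.14 ± 0.44 and CLEC2B by 2.07 ± 0.44. MUC5B changed by -2.06 ± 0.44 and SYT14 by -2.61 ± 0.49. KRT71 and KRT25, keratins of the hair follicle, fell, with 0 counts of KRT71 in DDX4-null tumors, at least 97.0-fold lower, and 3 counts of KRT25, 111-fold lower (95% counting interval 38.0 to 538.6). Neither reached 1 CPM in monolayer cells, as was so for 11 of the 270 called genes and 894 of the 12942 tested. The count of called genes was 26 without control tumor 3, 47 without control tumor 2, 134 without control tumor 1, and 129 without DDX4-null tumor 2 or 3. With library totals in place of TMM, 97 rose and 168 fell.

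Cell cycle genes were lower in DDX4-null tumors as lists, with few single genes past the threshold, and neither list passed with an estimated correlation (adjusted p = 0.731). Of 23 S phase genes 1 fell, and adjusted over the list alone 14 fell, with a mean log2 change of -0.29 (adjusted p = 1.4e-08). The cell cycle transcription factor E2F1 fell from 43.7 ± 5.67 to 27.2 ± 3.56 CPM. Of 25 G2 and mitosis genes 2 fell, the spindle gene TPX2 at -0.56 ± 0.11 and the mitotic kinase AURKA at -0.44 ± 0.09, and 7 fell adjusted over the list alone (adjusted p = 2.0e-05). These 3 genes are on chromosome 20 in GENCODE v29 (GRCh38), and lost their call after changes were centred by chromosome and in some fits without 1 library. Over all these alternatives their largest adjusted p was 0.160 for E2F1, 0.129 for TPX2 and 0.172 for AURKA.

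Of 24 genes of the unfolded protein and integrated stress response 4 rose, and 9 adjusted over the list alone (adjusted p = 9.4e-08, and adjusted p = 0.236 with an estimated correlation). DDIT4 changed by 0.99 ± 0.19, DNAJB9 by 0.71 ± 0.14, DDIT3 by 0.42 ± 0.09 and DNAJC3 by 0.50 ± 0.11. Of 10 stem cell associated genes the transcription factors SOX4 (0.75 ± 0.14) and SOX9 (0.58 ± 0.12) rose, and 3 adjusted over the list alone (adjusted p = 0.0038, and adjusted p = 0.236 with an estimated correlation). Of 28 hypoxia and glycolysis genes only the growth factor VEGFA rose, from 102 ± 19.6 to 170 ± 26.5 CPM, and 2 rose adjusted over the list alone (adjusted p = 2.0e-05). None of 32 interferon response genes passed, alone or adjusted over the list alone, and their mean log2 change was -0.51 (adjusted p = 2.0e-05). The hypoxia and interferon lists both had an adjusted p = 0.731 with an estimated correlation.

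In 6 further tumor lists the list test passed while at most 1 member did. With the preset correlation, 9 of 35 splits of the tumor libraries, the real one included, gave as many passing lists. The highest other split gave 16, so the number of passing tumor lists did not set the real grouping apart. Ribosomal protein genes (mean log2 change 0.22, adjusted p = 6.9e-05), mitochondrially encoded genes (0.28, adjusted p = 0.0133), fibroblast markers (0.85, adjusted p = 0.0077) and complement genes (0.39, adjusted p = 0.0471) were higher. Oxidative phosphorylation genes (-0.12, adjusted p = 0.0139) and antigen presentation genes (-0.24, adjusted p = 0.0466) were lower. Each of these 6 had an adjusted p = 0.731 with an estimated correlation. Adjusted over the list alone, 2 complement genes rose, and 0 members of the other 5 lists passed with edgeR. CD55, which limits complement, rose by 0.46 ± 0.10. Fibroblast markers, ribosomal protein, complement and antigen presentation genes no longer passed without DDX4-null tumor 1 or with stromal markers as a covariate. The covariate was the mean log2 CPM of the fibroblast, endothelial and pericyte, and leukocyte markers. For fibroblast markers the loss with the covariate therefore follows from its construction and tells nothing. In DDX4-null tumor 1 the mean log2 CPM of fibroblast markers was 6.76 against 4.93 to 5.09 in the other 3. Mitochondrially encoded genes no longer passed without DDX4-null tumor 2, where mitochondrial genes held 5.99% of counts against 3.60% to 4.30% in the other 3, or without control tumor 4. Of 18 alternatives the call was lost in 8 for antigen presentation, 6 for complement, 4 for fibroblast markers and 3 for each of the other lists of this paragraph.

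The interaction test called 7181 of 13603 genes, whose change from control to DDX4-null libraries differed between tumors and cells. Of these, 3532 had a more positive change in tumors and 3649 a more negative one. Chromosome 7 genes had a median log2 change of -0.75 in DDX4-null monolayers and 0.01 in DDX4-null tumors. The contrast therefore cannot tell an effect of the setting from a difference of cell population between both DDX4-null groups. CXCL5 had an interaction contrast of 10.03 ± 0.61, ZNF222 of 8.94 ± 0.68, MUC5B of 8.42 ± 0.63 and CA9 of 7.87 ± 0.87. LEF1 (-12.79 ± 0.84), LCP1 (-11.30 ± 0.27), CADM1 (-11.27 ± 0.55) and the epidermal keratin KRT6A (-11.16 ± 1.65) had the most negative ones. ZNF222, LEF1, CADM1 and KRT6A had 0 or 1 counts in a group, so the size and rank of their contrasts depend on the small count that the fit adds and are not measured values. As lists, NF-kB and cytokine genes had a more positive change in tumors (adjusted p = 8.5e-16, and adjusted p = 0.0280 with an estimated correlation). S phase genes (adjusted p = 3.5e-14) and G2 and mitosis genes (adjusted p = 8.5e-16) had a more negative one, each with an adjusted p = 0.0855 with an estimated correlation. With library totals the median contrast of all genes was -0.16, and 2721 contrasts were positive and 4404 negative.

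Genes called in both settings moved in one direction little more often than independent lists would. Of 12397 genes tested in both, 56 rose in both against 40.5 expected (one-sided Fisher's exact p = 0.0024), and 51 fell in both against 45.8 expected (p = 0.193). Another 89 changed in opposite directions against 86.2 expected. Fisher's test takes genes as independent, which they are not, so its p-values may be too small. Without 1 library the genes of one direction went from 107 to between 10 and 120, and were fewer than those of opposite directions without control tumor 1 (47 against 52) or DDX4-null tumor 2 (46 against 48). Across these genes, which are not independent replicates, the Pearson correlation of the log2 changes was 0.12 and the Spearman correlation -0.03. The Pearson correlation was 0.0047 with a filter at 5 CPM and 0.285 in the model of all 16 libraries. TCN1, KIRREL3, ZFPM2 and KRT75 rose in both, the last by 9.36 ± 0.16 in cells. The growth factor binding protein IGFBP2 rose by 3.04 ± 0.61 in tumors and from 3 counts to 24.3 ± 4.78 CPM in cells, and EVC2 fell in both. NNMT and SLC44A3 rose in cells and fell in tumors, by 1.72 ± 0.35 and 1.69 ± 0.32 on the log2 scale, and the mucin MUC2 and SHISA2 fell in cells and rose in tumors.

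**Figure D3:**
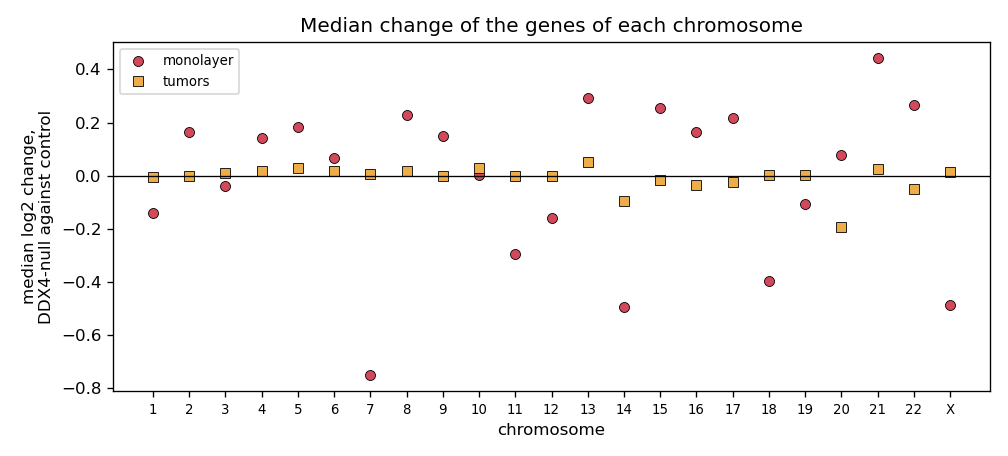
Points give the median log2 change of the genes of each chromosome (GENCODE v29) with at least 1 CPM in monolayer, DDX4-null against control, in monolayer (circles) and tumors (squares). Medians in monolayer reached -0.75 for chromosome 7 and 0.44 for chromosome 21, and in tumors the lowest was -0.19, for chromosome 20.

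Changes in monolayer cells followed chromosomes. The SD of the 23 chromosome medians was 0.30 in monolayer and 0.050 in tumors, against at most 0.064 and 0.024 in 1000 shuffles of genes over chromosomes. Between control tumors and control cells it was 0.138 against at most 0.058, so chromosome-wide differences were not limited to DDX4-null libraries. Chromosome 7 genes had a median log2 change of -0.75 in DDX4-null monolayers and 0.01 in DDX4-null tumors, and those of chromosome 14 of -0.49 and -0.10. After centring by chromosome the chromosome 7 genes IL6, SEMA3C and FZD1 changed by -3.53, -2.09 and 2.12 in monolayer.

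Control tumors differed from control monolayer cells in cytokine and stress genes, and in stroma genes whose lists did not pass with an estimated correlation (adjusted p = 0.0647 for fibroblast markers). The list of erythroid, muscle and fat markers did not pass, with 5 higher and 4 lower of 9 tested (adjusted p = 0.0760). It did pass with no filter, a filter at 5 CPM or a replicate block, and without control tumor 2, 3 or 4. The collagen COL1A2 had 1 count in control cells and 259 ± 57.7 CPM in control tumors. Among the largest single changes, the muscle genes MYH4, MYH1 and TNNT3, the metalloprotease MMP2 and the secreted IGFBP7 had 0 counts in control cells and were at least 887-fold, 690-fold, 372-fold, 443-fold and 781-fold higher in tumors. Reads of the host can be counted on human genes, so these rises need not be changes of the tumor cells. Of 12858 genes tested, 4354 were higher and 3986 lower in tumors. With library totals the median change was 0.19, and 5569 were higher and 2870 lower.

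Of 17 fibroblast markers 15 were higher (adjusted p = 1.6e-25), as were 10 of 13 endothelial and pericyte markers (adjusted p = 0.0026) and 8 of 9 leukocyte markers (adjusted p = 0.00029), with the same counts adjusted over the list alone. With an estimated correlation these had an adjusted p = 0.0647, an adjusted p = 0.125 and an adjusted p = 0.270. All 27 tested NF-kB and cytokine genes were lower in tumors, also adjusted over the list alone (adjusted p = 3.3e-57, and adjusted p = 0.0076 with an estimated correlation). IL6 changed by -8.11 ± 0.18, IL1B by -7.53 ± 0.18 and the iron carrier LCN2 by -9.41 ± 0.19, and the interleukin IL20 and the hormone FGF21 had 0 counts in tumors. Of 23 stress response genes 21 were lower and 1 higher, also adjusted over the list alone (adjusted p = 4.2e-24, and adjusted p = 0.0201 with an estimated correlation).

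S phase genes were higher in 19 of 23 cases and lower in 1, with 20 and 1 adjusted over the list alone (adjusted p = 1.3e-10), and interferon response genes higher in 26 of 32 and lower in 3, also adjusted over the list alone (adjusted p = 0.00015). With an estimated correlation these had an adjusted p = 0.270 and an adjusted p = 0.570. Mesenchymal and hypoxia genes were higher and p53 targets, integrins, ribosomal protein genes, histones, immediate early genes and stem cell associated genes lower, at adjusted p from 0.0035 to 0.0481. With an estimated correlation none of these 8 passed, with an adjusted p from 0.124 to 0.753. Of 16 alternatives the call was lost in 8 for mesenchymal, 7 for hypoxia and 5 for integrin genes.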

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

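All tests weighed here were chosen as tests after the result was seen, except the regrouping test of genes shared by cells and tumors. Some of them use fits that were fixed as alternatives beforehand. The test of cell cycle genes without members on chromosomes 14 and 20 was written before its own value was seen. Its pattern and its chromosomes were nevertheless taken from the tumor results. The limits of the other tests chosen afterwards were also set after values had been seen.

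The contrasts here are fitted, and those of genes with 0 or 1 counts in a group (ZNF222, LEF1, CADM1 and KRT6A) are set in size by the small count that the fit adds. The interaction test found 7181 genes whose change from control to DDX4-null libraries differed between tumors and cells, and 8 of them are named. Their contrasts were 10.03 for CXCL5, 8.94 for ZNF222, 8.42 for MUC5B and 7.87 for CA9, and -12.79 for LEF1, -11.30 for LCP1, -11.27 for CADM1 and -11.16 for KRT6A. Of 100 draws of genotype labels only the real one (1) gave as many genes, and the highest other draw gave 7141. The 3 other draws that kept the monolayer groups whole gave 6428 to 7141 genes, while the 96 draws that mixed them gave at most 0 with edgeR. The outcome follows from the monolayer groups, so these draws do not exclude chance for a difference between the tumor and the cell effect.

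The first pattern was that many genes changed in DDX4-null monolayers and few in DDX4-null tumors, with 1 of 35 splits giving as many genes in monolayer (8756, highest other 0) and 1 of 35 in tumors (270, highest other 7). An unrelated cell line in the DDX4-null monolayer libraries was argued against by STAT3, STAT5A and STAT5B, which PC3 cells lack, with 0 counts together in these 4 libraries. After centring on a running median, 71.8% of the monolayer calls passed with their sign, so shifts shared by many neighbouring genes did not account for all calls. Centring cannot remove losses of a few genes or effects of dosage on genes elsewhere. Chromosome dosage as the whole cause therefore stays open. The slope of the tumor chromosome medians on the monolayer ones was 0.0138 ± 0.0358 (SE), so the DDX4-null tumors may hold a cell population other than the DDX4-null monolayers that were sequenced. Selection among cells during tumor growth, a different clone and a mislabelled group stay open, as does an effect of DDX4 loss that depends on the setting. Chromosome medians also differed between DDX4-null and control monolayers, with an SD of 0.30 against at most 0.064 in shuffles. The monolayer calls therefore cannot be told apart from a difference between clones that is unrelated to DDX4.

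The next pattern was the set of genes changed in DDX4-null tumors. With stromal markers as a covariate 93.7% of the calls passed again with their sign, which argues against host stroma as the whole cause, while reads of other host tissue stay open. Without DDX4-null tumor 1, 81.5% of the calls passed again, so this library alone was not the cause, although without control tumor 3 only 26 genes passed. On chromosomes 14 and 20, 66 of 69 called genes fell, and 23.2% of these calls passed after centring by chromosome because the median absolute log2 change went from 0.49 to 0.36 at a median SE of 0.093, and since these genes were chosen for passing before, the change that remained does not decide against a shift of these chromosomes, which stays open. On other chromosomes 82.6% of the calls passed, at a median of 0.75 before and 0.74 after.

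The last pattern was the lower level of S phase and mitosis genes in DDX4-null tumors. Both lists together, without members on chromosomes 14 and 20, still passed at the preset correlation (42 genes, mean log2 change -0.23, adjusted p = 3.8e-08). The lower mean was therefore not limited to members on these chromosomes. The larger adjusted p of both lists was 2.1e-05 without DDX4-null tumor 1 and 1.6e-05 with stromal markers as a covariate, which argues against that library and against host stroma. With an estimated correlation the joint test gave an adjusted p = 0.746, and 9 of 35 splits of the tumor libraries, the real one included, gave as many passing lists (12 lists, highest other 16). The splits count lists of any kind, so they do not address the cell cycle genes alone. Given the joint test with an estimated correlation, variation of cell cycle activity between single tumors may account for the pattern and a DDX4 effect stays open.

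In monolayer 13 of 35 splits, the real one included, gave as many passing lists (8 lists, highest other 10). The others among these swapped 1 library between the groups and so kept part of the genotype difference. Their number therefore cannot decide whether chance gives as many lists. Splits that mixed the genotypes evenly gave 0 to 4 lists. For control tumors against control cells, 1 of 35 splits gave as many genes (8340, highest other 0) and 1 of 35 as many lists (15, highest other 14). For genes changed in one direction in cells and tumors, 1 of 100 draws gave as many (107, highest other 0 with edgeR). This follows from the monolayers, since mixing their groups ends nearly all calls; with the monolayer groups kept, other tumor splits gave at most 2, and the opposite direction gave 89.

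Single libraries stood apart from the other 3 of their group by the gap to the nearest one as a share of the group's range. Chance gives this in about 1 of 20 groups, and it was found in 4 of 24 library measures, 3 of 133 list means and 16 of 291 gene levels. DDX4-null monolayer 2 had 7.73% of its counts in the top 10 genes, 6.05% in mitochondrial genes, a mean log2 CPM of mitochondrial genes of 11.43 and 18.8 CPM of RNF43. DDX4-null tumor 1 had 0.590% of its counts in genes under 1 CPM in monolayer, a mean log2 CPM of fibroblast markers of 6.76, 13.5 CPM of LCP1, 15.6 of SHISA2 and 3.82 of SFRP1. Control tumor 4 had only 0.246% of its counts in genes under 1 CPM in monolayer. Control tumor 3 had 0.775 CPM of TCN1 and 4.61 of SFRP1, and control tumor 1 had 0.418 CPM of KIRREL3. DDX4-null tumor 4 had 3.82 CPM of ZNF222 and 127 of VEGFA, and DDX4-null tumor 3 had 0 CPM of KRT6A. Control monolayer 4 had 34.2 CPM of PRAME, 36.3 of TP53I3 and 2.13 of ZFPM2. Control monolayer 2 had 1743.8 CPM of NRP1 and a mean log2 CPM of immediate early genes of 6.08, and DDX4-null monolayer 4 had 109.9 CPM of NDUFA4.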

How the results depend on the processing

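The centring of changes and, for lists, the stromal covariate and the test on genes of at least 1 CPM in monolayer were chosen after seeing the data. With a 2-fold threshold the counts were 2815 in monolayer, 66 in tumors, 3081 for the difference and 2413 for control tumors against cells, by the construction of the threshold. In tumors the count of 270 became 883 with DESeq2, 808 (470 up, 338 down) in the model of all 16 libraries and 168 after centring on a running median, and the count of 107 shared genes became 315, 321 and 60 in that order, and 69 with centring by chromosome, against 304, 274, 64 and 65 in opposite directions. The cause was not tested. With an estimated correlation 1, 0 and 2 lists passed in monolayer, tumors and control tumors against cells, and 6, 2 and 6 had an unadjusted p under 0.05.

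Leaving out 1 library gave 8315 to 8891 genes in monolayer, 26 to 289 in tumors, 6719 to 7313 for the difference, 7757 to 8331 between controls and 10 to 120 shared genes. Fewer libraries lower the power, but the counts differed by library: 26 without control tumor 3, 47 without control tumor 2, 134 without control tumor 1 and 129 without DDX4-null tumor 2 or 3, with 10, 17, 47, 46 and 51 shared genes against 7, 16, 52, 48 and 45 in opposite directions, so the excess of 107 against 89 was not kept in every fit. In these fits 137 calls of named tumor genes were lost and 167 were kept, and no named gene or passing list turned its sign in any alternative. Lists numbered 8 in every monolayer fit, 10 to 13 in tumors and 12 to 16 between controls.

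DDX4 in tumors, at 0.01 on the log2 scale, changed sign to -0.0121 with library totals, to -0.0342, -0.0396 and -0.0089 without control tumor 2, 3 or 4 and to -0.0449 and -0.0386 without DDX4-null tumor 1 or 4, with a highest value of 0.12, so its sign was not determined, and in monolayer it ranged from -0.27 to -0.026 without 1 library and was -0.33 with a pseudocount of 0.1 CPM. The correlation of changes across genes was 0.0047 with a filter at 5 CPM, 0.285 in the model of all 16 libraries and 0.102 to 0.170 without 1 library.

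No pairing by replicate number was seen, since same-numbered samples correlated from -0.16 to 0.27 and differently numbered ones from -0.33 to 0.31. So few pairs cannot exclude a pairing. With the number as a replicate block the counts were 8883, 425 (258 up, 167 down), 7330 and 8332 genes, 156 shared genes and 8, 16 and 15 lists. Depth limits genes near the floor such as DDX4. Of changes of 0.5 on the log2 scale 38.8% were recovered in simulated tumors, where the common coefficient of variation between replicates was 0.147 against 0.113 in monolayer.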

Other observations

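All tests in this part were chosen after the result was seen.

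Neighbouring genes moved together in DDX4-null monolayers. Counting runs of at least 4 neighbouring genes that all rose or all fell by at least 2 on the log2 scale, 8 runs with 37 genes were found, against at most 1 in 100 shuffled orders, 0 in DDX4-null tumors and 3 between control tumors and control cells. On chromosome 11 the clathrin assembly gene PICALM fell from 153 ± 7.03 to 4.44 ± 0.666 CPM and EED, a subunit of a histone methyltransferase complex, from 17.9 ± 0.492 to 0.516 ± 0.135 CPM. In DDX4-null tumors these had 145 ± 16.9 and 20.5 ± 4.97 CPM, near control tumors at 130 ± 12.2 and 18.0 ± 0.985 CPM. On chromosome 19 a run of 7 kallikrein genes, which encode secreted proteases, rose, with KLK5 from 0.150 ± 0.105 to 81.7 ± 7.41 CPM. On chromosome 4 the chemokine genes CXCL1, CXCL2, CXCL3 and CXCL5 fell together. These genes were chosen after their values were seen.

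STAT3, which was read in 0 monolayer libraries, had 5.88 ± 0.394 CPM in control tumors and 7.33 ± 3.36 CPM in DDX4-null tumors, with a highest library of 12.3 CPM. Together with STAT5A and STAT5B it had 613 counts in control tumors and 569 in DDX4-null tumors. Since PC3 cells lack these genes, the reads point to host reads counted on human genes, and not to STAT3 turned on in tumor cells.

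A hypothesis was that a share of the cells in DDX4-null tumors is like the DDX4-null monolayer cells. In 25 genes with at least 10 CPM in DDX4-null monolayers, under 0.2 CPM in control monolayers and under 0.5 CPM in control tumors, the median excess of DDX4-null over control tumors was 1.12% of the monolayer level (95% bootstrap interval over genes 0.507% to 2.86%, which leaves out the spread between tumors). With 0.5 CPM as the limit in both controls it was 1.48% in 33 genes. For the mean levels of these tumors, a share of over 5% is argued against if these genes keep their level in tumors, which was not tested. Silencing of the genes in tumors may also account for the low values.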
